A study of Mus musculus with 8 samples.

How the data were processed

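Open chromatin was measured by ATAC-seq, in which a transposase inserts sequencing adapters into accessible DNA, in mouse embryonic stem cells. The 8 samples form 4 groups of 2 replicates. In the first pair of groups, cells of the v6.5 line in which doxycycline shuts off Ubc9, the conjugating enzyme of the SUMO pathway, were taken after 72 hours of the drug and compared with control cells of the same line. The labels give doxycycline for the depletion only, so an effect of the drug itself cannot be separated from that of the depletion. In the second pair, cells lacking the linker histones H1.2, H1.3 and H1.4 were compared with wild-type cells. Per the labels' protocols, cells had spent 4 passages in 2i/LIF medium, each reaction used 50000 cells, and libraries were amplified for 12 PCR cycles.

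Per the submitters' processing notes, the tools used were CASAVA 1.8.2, Bowtie2, Picard and MACS 1.4.2-1, with the genome build mm10. How each tool was set, and whether read positions were shifted for the transposase, is not given in the sources used here. Per the labels, each deposited list was made from both replicates of its group, so there is 1 list per group, no spread between replicates can be had, and no test or p-value is given for any difference. Each region in the lists has a position and a score that the authors deposited. The lowest deposited score is 50, and the score was read as the peak caller's, minus 10 times log10 of p, for which 50 stands for a p of 1e-05. It was used only to describe, rank or filter regions within a list. The read depth behind the lists is unknown, and a deeper library yields more peaks.

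How the replicates were combined is not stated, and the values differ in form between the pairs. In the lists of the Ubc9 pair, 90.8% and 92.0% of the deposited scores fall on multiples of 0.005 (tolerance 1e-05) and 45.5% and 46.3% on multiples of 0.01. In the H1 lists all scores fall on multiples of 0.01, regions are as short as 1 bp, and 1475 and 1173 regions repeat a peak name. The distinct names are 73.0% and 74.1% of the highest peak number. Widths, covered lengths and numbers of regions were therefore compared only within a pair.

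Regions of the lists of a pair were called shared when they overlapped by at least 1 bp, and unshared otherwise. Shares carry exact (Clopper-Pearson) 95% binomial intervals, which cover counting error only. Genes were the 21883 protein-coding genes of a RefSeq table for GRCm38.p6, whose coordinates are those of mm10. That table has no strand, so the promoter windows fixed beforehand were replaced by windows of 1000 bp on each side of both annotated ends of a gene, called gene ends here. Between 7.96% and 9.40% of the genes with a gene-end peak had peaks at both ends. A region overlapping no gene end was called inside a gene or outside genes.

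Of 17 gene lists fixed before the data were examined, 463 members matched the table and 14 did not. For each list and pair, members with a gene-end peak in the perturbed list were counted among those with none in the control list, and members without one in the perturbed list among those with one in the control list. Each count is given with its percentile, the percent of 10000 random lists with a lower count, drawn from genes in the same state. The random lists were not matched for the score of the peaks. The percentile describes these lists of peaks and is not a p-value. Of the 68 counts, at most 0.68 would be expected to reach percentile 99 at random, since some small lists cannot reach it, and 6 did. The genes named are the targeted genes, up to 4 members per gene list and pair with a gene-end peak in 1 list only, by score, the 8 highest-scoring genes with a gene-end peak in 1 list only per direction, and the 5 genes with the largest and the 5 with the smallest difference in unshared regions within the gene and 10 kb on each side. Some genes that these rules pick are not reported here. Any other gene named was chosen after its values were seen.

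A peak that crosses the edge of a gene-end window in 1 list only can mark a gene as differing although the peak itself is shared. This held for 61, 25, 26 and 33 of the genes with a peak only in the Ubc9-depleted, Ubc9-control, H1 triple-knockout and H1 wild-type lists, and named genes of that kind are pointed out. The overlap and counting steps were tested on simulated data. All 13673 regions planted in the Ubc9 pair were recovered, as were all 16311 in the H1 pair. This was fixed in advance, since the same overlap step had first removed planted regions that met another region. A separate comparison of the overlap step with a direct check of every pair of simulated regions found 0 that disagreed. Of regions removed in the simulation, 14009 of 14009 were found in the Ubc9 pair and 16516 of 16590 in the H1 pair. In the Ubc9 pair this too was fixed in advance. Regions kept were moved by at most 20 bp, and gaps in its control list are at least 263 bp. Of 10 lists of 20 genes in which the share of changed genes was raised 5-fold over 10%, 9 in the Ubc9 pair and 7 in the H1 pair reached percentile 99. Of 200 lists in which that share was left at 10%, 0 and 1 did. The calculations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.

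The alternatives tried were a stricter score, a larger minimum overlap, a distance of 500 bp, merged regions, equal numbers of top-scoring regions, other gene-end windows, and autosomes only. Added after the data were seen were the edge check above, the exclusion of chromosomes that stood apart, and random lists that keep neighbouring members together. Shares of sequence motifs were not analysed here, since no genome sequence was used. Random draws planned for regions that differed in both pairs were not used, because a region enters the comparison only if some list holds it, which ties the pairs together by construction.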

Results

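The deposited lists of the Ubc9 pair held 48730 regions for depleted cells and 46847 for control cells, covering 26.8 and 21.7 Mb. Those of the H1 pair held 58039 for triple-knockout cells and 55489 for wild-type cells, covering 17.3 and 17.5 Mb. Each list pools 2 replicates, so no difference below has a replicate check, and "only" means that a region had no overlapping partner in the other list of its pair. Scores are the authors' own, per peak, and rank peaks within a list. Coordinates are mm10.

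The targeted genes came first. H1f2, H1f3 and H1f4 (H1.2, H1.3 and H1.4, chromosome 13) had a gene-end peak in all 4 lists. Over the genes themselves, looked at after the gene ends, regions of wild-type cells covered 725 bp of H1f2 and 242 bp of H1f3 and those of knockout cells 0 bp, while H1f4 had 38 bp and 20 bp. Of the 19 genes of the SUMO pathway list, 17 had a gene-end peak in each list.

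The comparison of Ubc9-depleted with control cells asks which chromatin opens or closes when SUMO conjugation is lost. Genes of the 2-cell embryo stood out: 16 of the 45 members without a control peak had a gene-end peak only in depleted cells. The median of random lists was 5, and 0 of 10000 had as many. None of the 10 members with a control peak lacked one in depleted cells. The highest-scoring of the 16 were Gm2016 (chromosome 12, score 319.4), Zscan4f (306.4), Zscan4c (298.4) and Zscan4d (278.7). Zscan4 genes encode zinc-finger proteins that mark the 2-cell stage and lie together on chromosome 7. Within the 0.702 Mb from 10800740 to 11502318 there, the depleted list held 44 regions, 33 of them only in that list, and the control list 17, with 6 only there. The 16 genes include near-identical copies, whose reads may not be told apart, and also Zfp352 (chromosome 4, score 130.8), named after its value was seen.

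**Figure D1:**
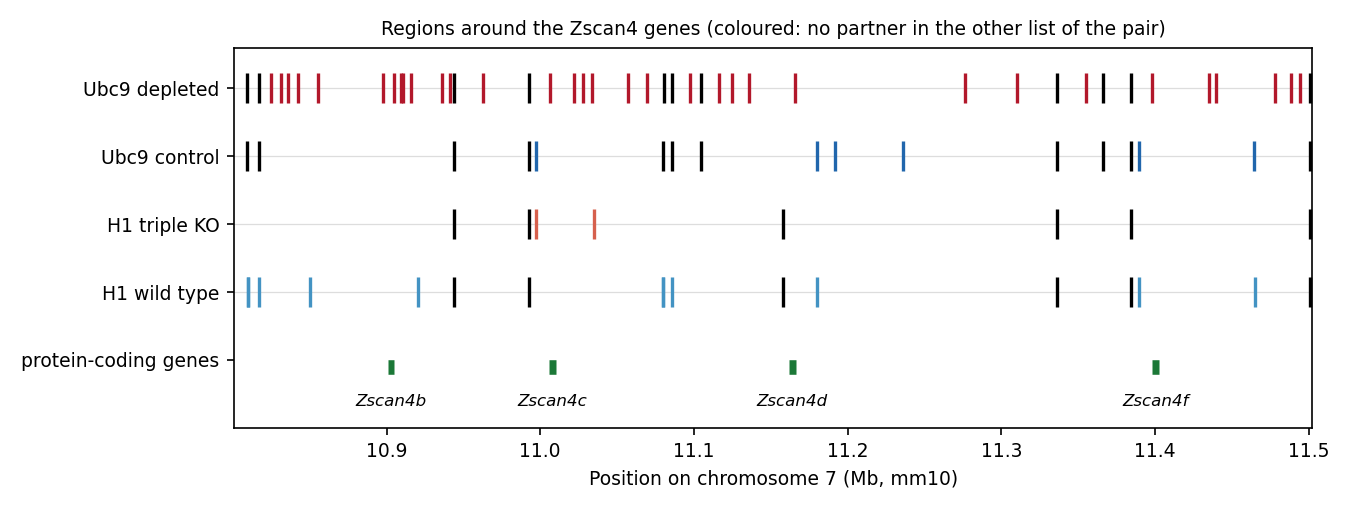
Map of chromosome 7 from 10800740 to 11502318 (x axis, position in Mb), with a tick at the centre of each region of the 4 lists and the Zscan4 genes as green bars. Black ticks overlap a region of the other list of the pair, and coloured ticks do not: 33 of 44 ticks in the Ubc9-depleted row are coloured, against 6 of 17 in the control row.

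Imprinted genes also had peaks only in depleted cells more often than random lists, 6 of 13 at percentile 99.85, with 1 of 18 the other way. Peg10 and Sgce, 2 neighbours on chromosome 6 that share a peak (score 74.3), and Cdh15 (78.2) were among the 6, and Rasgrf1 (91.7) was the gene with a control peak only. Interferon-response genes went the other way. Of 14 with a control peak, 7 had none in depleted cells, a count that 0 of 10000 random lists reached. Isg20 (score 104.6), Usp18 (91.1) and Irgm1 (89.5) led them, and Oas1a, whose peak was shared but crossed a window edge, was the only member counted with a depleted-only peak. With a score of at least 100 and windows of 2500 bp outside and 500 bp inside the gene, 12 genes of the 2-cell list still stood at percentile 99.99, while the imprinted count became 1 (percentile 37.57) and the interferon count 0.

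Counts for lists of pluripotency and lineage genes stayed below percentile 99. Of 28 pluripotency genes with a control peak, 4 had none in depleted cells (percentile 84.39), among them Utf1 (score 126.6), Tdgf1 (109.8, a window-edge case) and Dppa3 (105.7), while Trim71 (90.5) was 1 of 12 with a peak in depleted cells only (22.94). Of 9 trophectoderm genes with a control peak, Gata3 (100.6), Bmp4 (92.5) and Cdx2 (91.3, a window-edge case) had none in depleted cells (97.09), and of 16 without one, Lgals3 (103.3) had a peak in depleted cells only (14.39). Mesoderm and endoderm genes with a peak only in depleted cells numbered 5 of 19 (94.38), with Mesp2 (131.1), Mesp1 (83.1) and Twist1 (79.2), against Cer1 (87.7) in control cells only, 1 of 7 (56.85). Nes (113.7) and Zic1 (97.4) were among the 3 of 18 neural genes with a peak in depleted cells only (66.91).

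Primitive endoderm genes split evenly, with Col4a1 and Col4a2 (a shared peak, 141.7) in depleted cells only and Gata6 (128.7) and Thbd (106.4) in control cells only, 3 of 14 (79.68) and 3 of 11 (95.45) in all. Germline genes with a depleted-only peak numbered 5 of 25 (86.37), including Zp3 (187.7), Slc25a31 (174.0), Syce1 (160.8) and the window-edge case Taf7l. The primed-state genes Sfrp2 (146.4), Dnmt3b (134.0) and Grhl2 (61.6) had a peak in depleted cells only, 3 of 10 (91), and Lef1 (80.5) in control cells only, 1 of 11 (42.5). Hox genes numbered 5 of 27 in depleted cells only (81.26), led by Hoxa4 (224.8), Hoxa5 with Hoxa6 (a shared peak, 121.7) and Hoxc6 (a window-edge case), and 3 of 12 in control cells only (94.1). Of fibroblast and feeder cell genes, Col5a1 (265.6) and Loxl1 (63.4) had a peak in depleted cells only, 2 of 16 (44.02), and S100a4 (65.1) and Fbn1 (59.0) in control cells only, 2 of 4 (96.9). Among p53 targets Cdkn1a (61.0) was 1 of 18 with a control-only peak (24.19) and Gdf15, a window-edge case, 1 of 2 with a depleted-only peak (79.41). H1f5 (94.4) was the only other linker histone to differ, with a control-only peak (1 of 5, 67.64), and 0 of 27 housekeeping genes had a control-only peak.

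**Figure D2:**
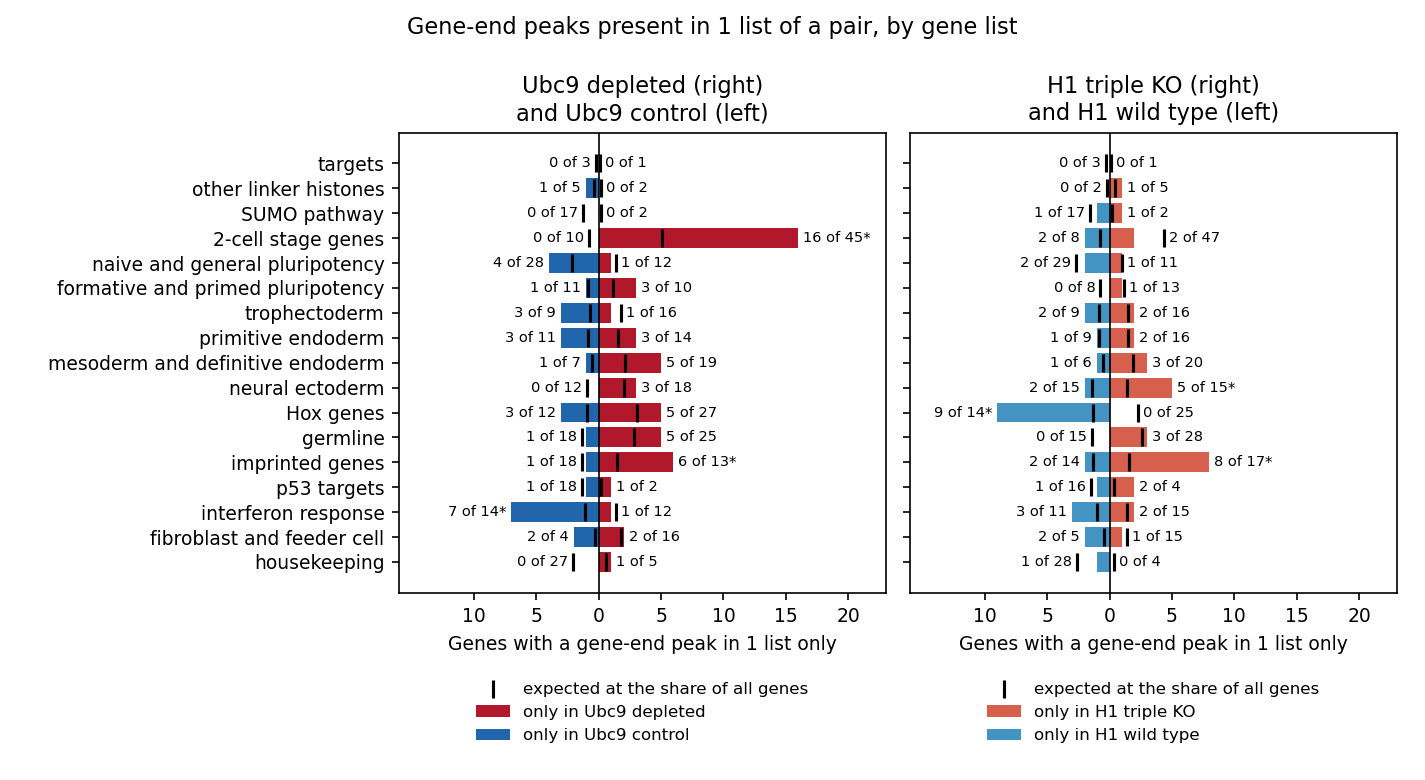
Number of genes of each list (y axis) with a gene-end peak in only 1 list of a pair (x axis, genes), in the Ubc9 pair (left panel) and the H1 pair (right panel). Bars to the right count genes with a peak only in perturbed cells and bars to the left only in control cells, each labelled with the number of genes that could have differed, black ticks give the number at the share of all genes, and * marks percentile 99 or above, as for 16 of 45 genes of the 2-cell list.

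Over the genome, 22218 regions (45.6%, interval 45.2 to 46.0) were only in depleted cells and 20276 (43.3%, 42.8 to 43.7) only in control cells. Of the depleted-only regions 69.6% (69.0 to 70.2) lay outside genes and 24.6% inside, against 50.3% (49.6 to 51.0) and 43.3% of control-only regions. Gene ends held 5.88% and 6.36%, against 36.6% of the shared regions of the depleted list. Among the 20% of regions with the highest scores in each list, 21.9% (21.1 to 22.7) of depleted regions and 6.07% (5.60 to 6.58) of control regions had no partner. Only 12.1% of depleted-only regions overlapped a region of H1 triple-knockout cells and 10.1% a region of H1 wild-type cells, while 58.5% and 63.3% of control-only regions did. Of the whole control list, 56.7% overlapped the depleted list, but 73.4% the H1 triple-knockout and 75.0% the H1 wild-type list. Of the whole depleted list, 54.4% overlapped the control list, and 51.6% and 50.3% the H1 lists. The depleted list thus stood apart from the other 3, and the cause was not tested. Gene-end peaks were only in depleted cells at 1161 genes and only in control cells at 880. With a score of at least 100 in the list counted, the numbers were 12001 and 9071 regions and 673 and 362 genes, and the difference in gene-end share changed sign. With equal numbers of top-scoring peaks, 13609 were only in depleted and 13585 only in control cells.

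**Figure D3:**
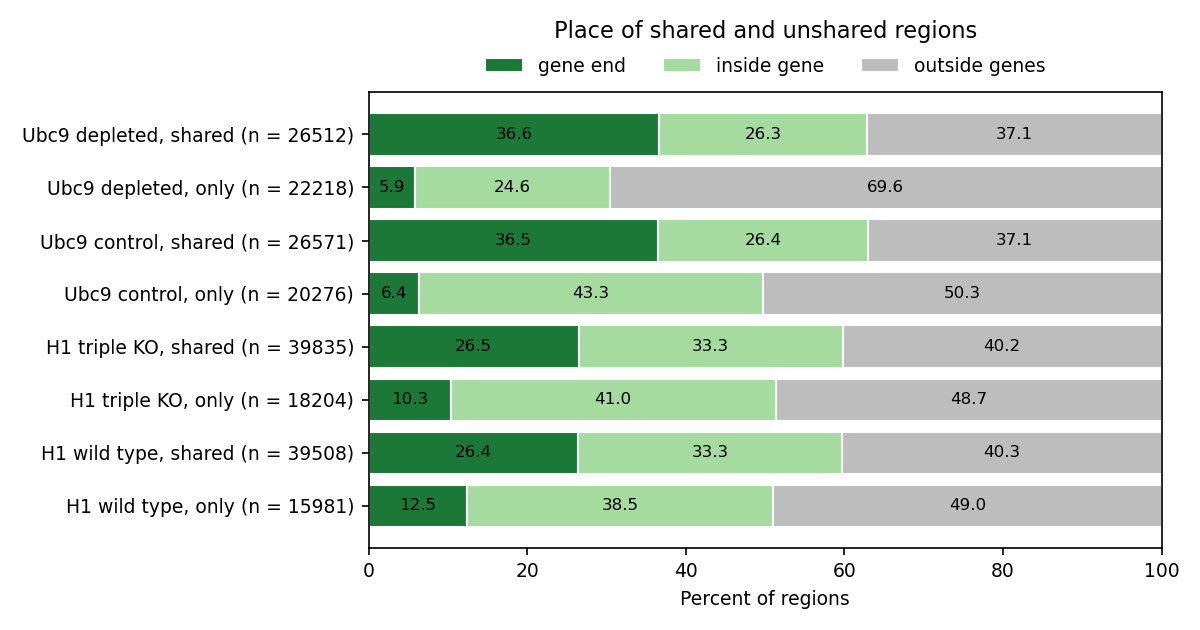
Percent of regions (x axis) at gene ends, inside genes and outside genes, for the shared and the unshared regions of each list (y axis, with the number of regions). Regions only in Ubc9-depleted cells have the largest part outside genes, 69.6%.

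By single genes, the largest surplus of depleted-only regions was at 2210408I21Rik, Alk, Nkain2 and Ralyl, each with 9 against 0, and Asic2 with 10 against 2. The largest deficits were at Tenm4 (4 against 27), Palld (1 against 18), Plcb4 (0 against 17), Pard3 (2 against 16) and Pde4d (8 against 22). All of these are long genes, from 356 to 1302 kb. Of the 8 top-scoring genes with a gene-end peak in depleted cells only, Mphosph9, Mrpl18, Lig1, Kdm2a, 4930453N24Rik and Ifna13 were window-edge cases, which left the predicted genes Gm46913 (score 771.2) and Gm52259 (569.8). Of the 8 in control cells only, Slc6a15, Mnat1, Gm8108 and Gpr174 were window-edge cases, which left Dync2h1 (431.7), a motor protein of cilia, Ankrd66 (370.8), Aplnr (361.2), the apelin receptor, and S100a1 (351.6).

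The comparison of H1 triple-knockout with wild-type cells asks what the loss of linker histones opens or closes. Hox genes, the regulators of body-axis identity, differed most. Of 14 with a wild-type peak, 9 had none in knockout cells, which 0 of 10000 random lists reached, and 0 of 25 had a peak in knockout cells only. All 7 Hoxa genes with a wild-type peak were among the 9, such as Hoxa9 (chromosome 6, 52223097 to 52227370, score 163.1), Hoxa13 (144.4) and Hoxa4 (134.2). Of the 7, Hoxa5 and Hoxa6 share a peak (128.3). Outside chromosome 6, Hoxb9 and Hoxd13, named after their values were seen, made up the rest, 2 of 7 at percentile 86.57.

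Imprinted genes had peaks in knockout cells only at 8 of 17 (0 of 10000 random lists as high), against 2 of 14 the other way. Peg3 and Usp29 of the 8 share a peak (71.6). Members did not all behave as in the Ubc9 pair. Cdh15 (58.8) had a peak in wild-type cells only and Rasgrf1 (67.45) in knockout cells only, each the reverse of the Ubc9 pair. Impact and Sgce had a perturbed-only peak in both pairs, Sgce at different ends of the gene. Among the 8 were Impact (score 232.8, a window-edge case), Commd1 (156.9) and Grb10 (91.6), while Igf2r (96.9) had a peak in wild-type cells only. Neural genes numbered 5 of 15 (percentile 99.1), including Dlx5 (103.9) and Nes (97.5), with Tubb3 (139.5) among 2 of 15 the other way. Without chromosomes 3, 6 and 8, which stood apart as given below, neural genes numbered 3 (percentile 89.13) and imprinted genes 6 (99.89). Under the stricter score with the wider outer window, both counts became 1 (46.81 for neural and 47.34 for imprinted genes), the Hox count stayed 9, and genes of the 2-cell list with a peak in wild-type cells only reached percentile 99.

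With windows of 1000 bp and no score minimum, gene-end counts of the 2-cell list were below percentile 99. Rnf168 (84.7) and Slc34a2 (80.2) had a peak in knockout cells only, 2 of 47 (percentile 6), and Zfp750 (156.5) and Calcoco2 (131.3) in wild-type cells only, 2 of 8 (83.36). In the Zscan4 interval on chromosome 7 the wild-type list held 17 regions, 11 of them only in that list, and the knockout list 8, with 2 only there. Of pluripotency genes, Tet1 (88.2) had a peak in knockout cells only, 1 of 11 (34.71), and Trim71 (133.5) and Tcl1 (72.9) in wild-type cells only, 2 of 29 (23.95). Interferon-response genes Usp18 (227.0), Irgm1 (111.0) and Isg20 (65.4) had a peak in wild-type cells only, 3 of 11 (92.67), and Zbp1 (123.2) was among 2 of 15 in knockout cells only (58.96). The p53 targets Phlda3 (155.3) and Cdkn1a (88.2) had a peak in knockout cells only, 2 of 4 (95.59), and Bbc3 (57.0) in wild-type cells only, 1 of 16 (20.73).

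The remaining lists lay below percentile 95. Foxa2 (104.6), Ttr (55.7) and Cited1 (76.2) of the primitive endoderm list differed, the last with a wild-type-only peak (1 of 9, 41.33) and the others with knockout-only peaks (2 of 16, 56.14). Gsc (127.5), Lhx1 (99.9) and Tbx6 (58.0) of the mesoderm and endoderm list had knockout-only peaks, 3 of 20 (72.39), and Twist1 (60.8) a wild-type-only peak, 1 of 6 (55.83). Tfap2a (123.3) and Syna (54.2) of the trophectoderm list had knockout-only peaks, 2 of 16 (55.97), and Cdx2 (79.0) and Eomes (75.8) wild-type-only peaks, 2 of 9 (80.82). Knockout-only peaks were at Ddx4 (173.9), Dpep3 (69.8) and Zp3 (66.1) of the germline list (3 of 28, 51.25), Pou3f1 (150.1) of the primed-state list (1 of 13, 28.43), and H1f1 (50.2), a remaining linker histone (1 of 5, 61.86). In the SUMO pathway list Senp1 (175.7) had a knockout-only peak, 1 of 2 (82.41), and Pml (109.6) a wild-type-only peak, 1 of 17 (19.47). Of fibroblast and feeder cell genes, Col5a1 (81.0) had a knockout-only peak, 1 of 15 (23.42), and Meox2 (109.2) and Tbx15 (86.4) wild-type-only peaks, 2 of 5 (93.26). Gusb (59.7) was the only housekeeping gene to differ, with a wild-type-only peak (1 of 28, 5.9).

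Unshared regions numbered 18204 (31.4%, interval 31.0 to 31.7) in knockout cells only and 15981 (28.8%, 28.4 to 29.2) in wild-type cells only. Gene ends held 10.3% (9.90 to 10.8) of the former and 12.5% (12.0 to 13) of the latter. Among the 20% with the highest scores, 3.15% and 3.11% had no partner. Gene-end peaks were only in knockout cells at 973 genes and only in wild-type cells at 1045. With a score of at least 100 in the list counted, 7903 and 6420 regions and 479 and 467 genes were unshared. The direction depended on the setting: a score of at least 100 in both lists gave 1167 knockout-only and 862 wild-type-only genes, and equal numbers of top-scoring peaks 10861 knockout-only and 11135 wild-type-only regions.

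The balance differed by chromosome. The ratio of knockout-only to wild-type-only regions was 3.19 on chromosome 3, 0.499 on chromosome 6 and 0.386 on chromosome 8, with a median of 1.14 over autosomes, and it was 1.05 on X and 0.180 on Y (11 against 61). All 16 windows of 10 Mb on chromosome 3 lay above the ratio of the other autosomes and all 13 on chromosome 8 below. On chromosome 6 this held for all 7 windows from 80 Mb on, where the ratio was 0.309, and chromosome 1 between 110 and 140 Mb had 471 against 128. The genes with the largest differences lay there. Iqschfp (19 against 1), Schip1 (18 against 1) and St6galnac3 (20 against 5) are on chromosome 3, and Cfap221 (12 against 0) and Gli2 (13 against 1) on chromosome 1. Tenm3 (2 against 29), Galntl6 (1 against 14) and Gse1 (2 against 15) are on chromosome 8, and Frmd4b (0 against 16) and Foxp1 (0 against 15) on chromosome 6. In the Ubc9 pair the ratio was 1.98 on chromosome 19, 1.41 on X and 4.57 on Y, with a median of 1.12 over autosomes.

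**Figure D4:**
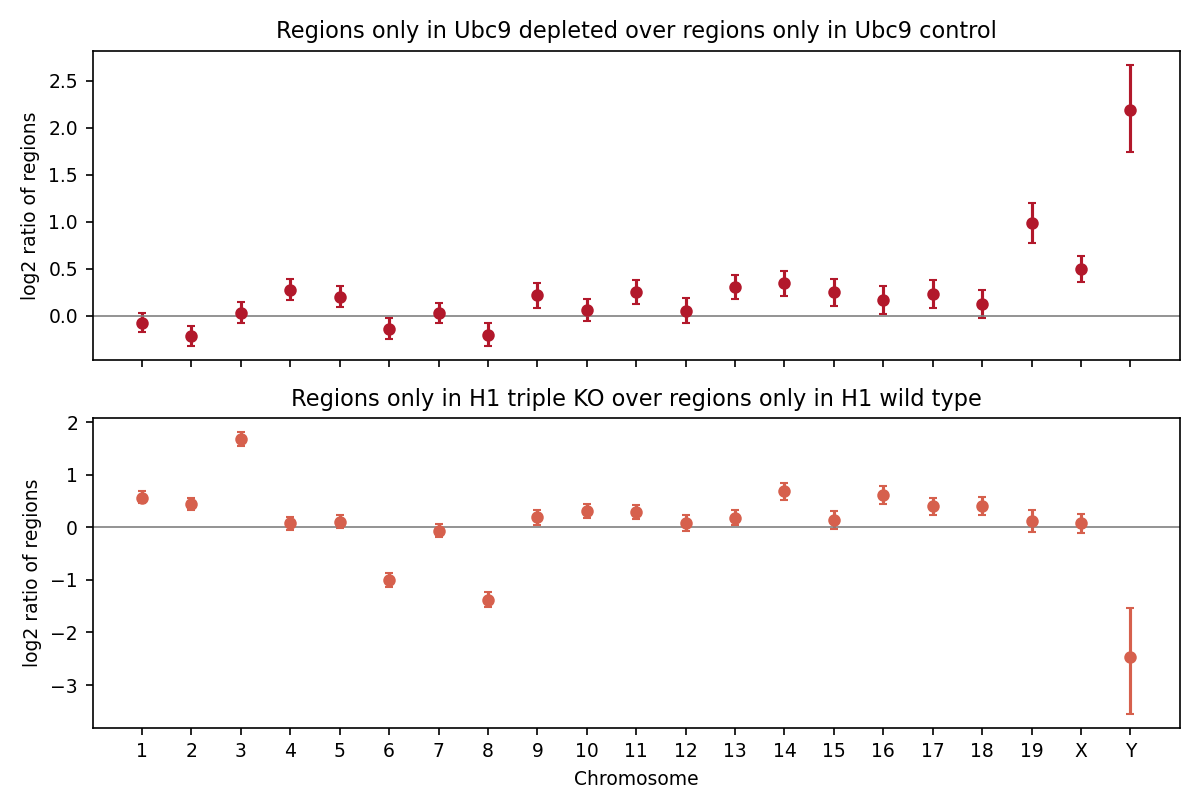
Log2 ratio of regions only in perturbed cells to regions only in control cells (y axis) for each chromosome (x axis), in the Ubc9 pair (top) and the H1 pair (bottom). Points are the ratios and bars exact 95% binomial intervals that cover counting error only, and in the H1 pair chromosome 3 lies at 1.67 and chromosome 8 at -1.37.

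Of the 8 top-scoring genes with a gene-end peak in knockout cells only, Clec11a, Acsm3, Vmn2r12, Mnat1 and Polg were window-edge cases, while Igsf10 (470.8, chromosome 3) and the adaptor Dok5 (365.7) were not. In wild-type cells only, Aktip, Osgin2, Ppm1h, Bcap31, Cmtm3 and Trpm3 were window-edge cases, which left Frmd4b (422.6, chromosome 6) and Gm49894 (389.9).

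Regions that were unshared in both pairs were compared last. Among 8268 such regions, 58.6% differed in the same direction, 1359 in both perturbed lists only and 3486 in both control lists only. Of depleted-only regions among them, 60.1% (58.0 to 62.1) were knockout-only rather than wild-type-only, against 42.0% (40.7 to 43.2) of control-only regions. Among 555 genes with a gene-end difference in both pairs, 52.6% differed in the same direction, with 148 genes in both perturbed lists only, 144 in both control lists only, and 150 and 113 in opposite directions. Of depleted-only genes among them, 49.7% (43.8 to 55.5) were knockout-only, against 44.0% (37.8 to 50.3) of control-only genes. These intervals overlap. The interferon-response genes Isg20, Usp18 and Irgm1 had a peak in both control lists only. With a score of at least 100 in the list counted, 309 regions were in both perturbed lists only and 953 in both control lists only.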

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

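No test was run here, and the count was picked out after the result was seen. Unplaced and unlocalized scaffolds, which no comparison above covers by chromosome, held 119 regions in the Ubc9-depleted list and 75 in its control. The exact 95% Poisson interval of the depleted count, 98.6 to 142, lies above the control count, and this is what drew attention to it, as a signal outside the main measurement above the level in control cells. Of these regions, 76 were only in depleted cells and 31 only in control cells. In the H1 pair the knockout list held 76 such regions and the wild-type list 109.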

How the results depend on the processing

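Alternatives added after the data were seen were the edge check, the exclusion of chromosomes 3, 6 and 8 or 19, X and Y, and the random lists that keep neighbours together. Of 87 values recomputed for the results that answer a comparison, 65 stayed within the limits set for a change, 20 moved and 2 changed sign. Every large shift but the last came with settings that use fewer peaks or members by construction. With a score of at least 100 in both lists, regions only in Ubc9-depleted, Ubc9-control and H1 wild-type cells numbered 14428, 13144 and 10062, and those in both perturbed or both control lists only 850 and 2133. With that score in the list counted only, the 4 lists in the order of the report had 12001, 9071, 7903 and 6420 regions and 673, 362, 479 and 467 genes, and the regions in both pairs numbered 309 and 953. With equal numbers of top-scoring peaks, 13609 were only in depleted and 13585 only in control cells, 10861 only in knockout and 11135 only in wild-type cells, the reverse of the order of 18204 and 15981, and 656 in both perturbed lists only. As a percent of the peaks kept, depleted-only peaks ranged from 37.5 to 45.7 over the alternatives. Genes with a peak in knockout cells only, 973 against 1045 in wild-type cells only, became 1167 against 862 with a score of at least 100 in both lists. In the Ubc9 pair 3 gene list counts reached percentile 99, and 1 did with the stricter score and wider outer window. In the H1 pair 3 did, and 1 without chromosomes 3, 6 and 8. The gene-end share of depleted-only minus control-only regions, -0.480 percentage points, became 0.172 with 500 bp windows and 0.0485 with the stricter score in the list counted. The cause was not tested.

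No paired analysis was possible because each list pools both replicates of its group. For the same reason leaving out a replicate was not run, and motif shares were not run without a genome. The read depth behind the lists is unknown, so a region missing from a list was not detected there, not shown to be closed.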

Other observations

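The tests of depth, of weak calls, of a 2-cell-like state and of Hoxa neighbours of like score below were chosen after the result was seen, as were the gene families, the neighbourhoods and the first 20 Mb of chromosomes. By families named by the leading letters of the symbol, zinc-finger genes of the Zfp family stood out in depleted cells. Of 99 without a control peak, 32 had an unshared gene-end peak in depleted cells, against 10.6 expected from all genes, and 0 of 10000 random lists had as many. The other way, 17 of 298 Zfp genes had one only in control cells (21.9 expected). The 32 include Zfp352 of the 2-cell list. They also include Zfp600, Zfp992, Zfp991, Zfp988, Zfp979 and Zfp933, which lie together on chromosome 4 (146156827 to 147849126). Such neighbours are not independent, and the random lists here did not keep neighbours together. Wnt signalling genes followed with 6 of 14 in depleted cells only, against 1 of 5 in control cells only, and Zbtb genes with 5 of 11, against 1 of 30 in control cells only. Among olfactory receptor genes (Olfr), 13 of 26 with a control peak had none in depleted cells (1.91 expected, 0 of 10000 random lists as high). Of 1084 without a control peak, 8 had a peak in depleted cells only (116 expected). The peaks of the 13 scored 67.2 to 165.8. Over the whole control list, 73.6% of regions scoring 50.3 to 82.65 had no partner. The share was 62.5% up to a score of 108.21, 47.5% up to 149.74 and 26.7% up to 238.98. Random lists of families were not matched for score. A loss common to peaks of such scores therefore cannot be told apart from one particular to Olfr genes. Fgf genes had 5 of 12 in control cells only and 1 of 10 in depleted cells only, and Prss genes 4 of 10 and 0 of 29. Of 1474 genes of 5 large receptor, defensin and Skint families without a control peak, 13 (0.882%, interval 0.470 to 1.5) had a peak only in depleted cells, against 10.7% of all genes. In the H1 pair Ddx genes had 5 of 11 in knockout cells only and 4 of 26 in wild-type cells only, and Zfp genes 17 of 96 and 23 of 301. Of the families with at least 10 genes, 3 passed in depleted cells only (at most 1.04 expected at random among 104) and 3 in control cells only (at most 1.27 among 127). In the H1 pair 2 passed in knockout cells only (at most 1.07 among 107) and 0 in wild-type cells only (at most 1.19 among 119), near the number expected by chance.

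Within 50 kb of genes, pluripotency genes had 108 control-only regions (percentile 100) and 43 depleted-only regions (20.76). The control-only median was 50 at random loci, windows of the same lengths that start 50 kb before random protein-coding genes. Random loci were not matched for how many regions they hold in all. Around trophectoderm genes there were 48 control-only and 17 depleted-only regions (97.91 and 0.72). In the H1 pair the counts near pluripotency genes were high in both directions, with 77 knockout-only and 76 wild-type-only regions (99.54 and 99.97). Around Hox genes there were 22 wild-type-only and 3 knockout-only regions (99.74 and 2.67). SUMO pathway genes had 48 knockout-only and 26 wild-type-only regions (99.39 and 59.24), and p53 targets 38 wild-type-only and 32 knockout-only regions (99.32 and 88.35). These counts were picked from all 17 lists in both directions and pairs. The first 20 Mb of the autosomes, next to the centromere in the mouse, held 17% (16.4 to 17.5) of depleted-only and 11.9% (11.4 to 12.3) of control-only regions, and 14.8% and 12.5% of the whole lists. In the H1 pair the order was the other way, with 11.1% of knockout-only and 13.1% of wild-type-only regions.

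Regions only in Ubc9-depleted cells lay mostly outside genes. Weak calls are argued against as the whole cause. Among the 20% of regions with the highest scores, 21.9% of depleted and 6.07% of control regions had no partner. Of these, 77.3% (75.5 to 79.1) and 55.4% (51.2 to 59.5) lay outside genes. Among the 20% with the lowest scores, 64.4% of depleted and 73.6% of control regions had no partner, and 64.0% and 49.3% of these lay outside genes. A part due to weak calls therefore stays open. A 2-cell-like state in some of the cells is a candidate explanation for a small part. Around the 30 loci of the 2-cell list without a gene-end difference, 56 depleted-only regions lay outside genes. The median at random loci of the same lengths was 21 (0 of 10000 as high). These 56 are 0.362% of all depleted-only regions outside genes, and 21 of the 30 loci held any. Many lay at groups of related genes. Obox loci on chromosome 7 held 6, 6 and 3, and Tdpoz loci on chromosome 3 held 6, 4 and 2. The random loci were not matched for such groups, so the count is not independent of reads shared between copies. The 151 depleted-only regions around the whole list (random median 57) decide nothing, since that list had already stood out at its gene ends. The rest, an effect of doxycycline itself and reads shared between near-identical copies were not tested and stay open.

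The uneven split of the H1 pair by chromosome argues against a difference in depth alone, since the interval of the knockout share lay above 50% on 11 autosomes and below on 2. A difference in chromosome copy number between the lines may account for it on chromosomes 3 and 8. There the skew was as clear at gene ends, where 20.5% of unshared regions on chromosome 8 and 76.9% on chromosome 3 were knockout-only. The share was 50.2% on the autosomes other than 3, 6 and 8. Any cause acting on whole chromosomes would show the same, and no reads of input DNA were used here. Gene density of the chromosome could not be decided, with a Spearman rho of -0.365 over 19 autosomes. An effect of the knockout itself on these chromosomes was not tested and stays open.

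For the Hox genes with a wild-type peak only, an effect of linker histone loss on all Hox clusters cannot be told apart from one on the Hoxa cluster. Outside chromosome 6 the count, 2 of 7, stood at percentile 86.57 among random lists, but 7 genes are too few: the interval of this share, 3.67% to 71.0%, holds both the 9.23% of all genes and a large effect. Within 50 kb of the Hox genes outside chromosome 6 there were 6 wild-type-only regions, against a median of 5 at random loci (percentile 50.75). Whether a shift shared by the whole stretch from 40 to 60 Mb of chromosome 6 is the whole cause could not be decided. Of 33 other genes there with a wild-type peak of a score in the Hoxa range, 15.2% (5.11 to 31.9) had none in knockout cells. The share was 100% (59.0 to 100) of 7 Hoxa genes. These are neighbours in a single cluster that had drawn attention by this loss, and Hoxa5 and Hoxa6 share a peak. The 7 are therefore not independent, and the interval of their share is too narrow to set against the other. Whether a smaller shift of that stretch adds to the Hoxa result stays open too. The share among all 80 other genes there with a wild-type peak, 11.25% (5.28 to 20.3), could not be separated from the 8.76% on other autosomes. The stretch was not uniform. From 40 to 50 Mb 78 regions were knockout-only and 51 wild-type-only, and from 50 to 60 Mb, where the Hoxa genes lie, 34 and 79. A shift limited to the part around the Hoxa genes was not tested and stays open.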
